A study of Mus musculus with 210 samples.

How the data were processed

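The data are single-cell 3' RNA counts from mouse R1 embryonic stem cells in 210 samples of 8 sequencing runs, each sample a pool of wells of a 384-well plate. Cells were sorted as live single cells, 1 per well, and libraries were made by MARS-seq, per the labels' protocols. The authors deposited 1 table per run of raw counts per gene and well, from reads with molecular identifiers, with genome build mm10 per the submitters' processing notes. The aligner, the counter and the handling of identifiers are not given in the sources used here. The values are whole numbers, and their sums per well equal the totals in the deposited annotation. The authors also deposited forward and side scatter intensity of each sorted cell in instrument units, per the file headers, with no transformation recorded.

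The tables hold 56560 gene entries, of which 54553 name 1 gene and 54380 of these matched the mouse annotation by identifier. The other 2007 entries name 2 genes and took 1.747% of the counts. They were kept in library sizes and tests under their joint name, as in the case of Igf2, and stood for the listed gene in the lists. Gm42418, which overlaps ribosomal RNA, took 5.506% of the counts. Of 40512 wells, those of 1 pool belong to no sample used here and were left out. In 2 pools the title and the deposited annotation name different groups, and both were left out. Of 30 pools labelled empty 1 is among these, and the other 29 served as background, and 8 pools of run 6 entered no comparison, because their titles say only gastruloids, although the deposited annotation names them Gastruloid_AgW. No doublet calls were made, since wells were sorted with single cells. No well among 33528 with at least 500 counts had the same counts as another.

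A well was kept with at least 500 counts, at least 250 genes and at most 25% of counts from mitochondrially encoded genes, and wells that the deposited plate layout marks as holding no cell (4 per plate) were left out. Of 32490 sorted wells in the 11 groups, 29977 passed, with a median of 6533 counts and 3059 genes. The limit on mitochondrial counts alone removed 12 wells. In 360 wells without a cell the median was 290 counts and 24.2% reached 500 counts. In 5510 wells of empty pools the median was 339 and 31.3% reached 500 counts, whereas 1.11% reached 2000. In run 5, which alone holds the AggreWell groups, 79.2% reached 500 and 12.37% reached 2000, so there the higher minimum does not clear the background either. Wells near the minimum of 500 can therefore hold background, and wells with at least 2000 counts were tested as an alternative.

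Counts were summed over the kept wells of each group and run, which gave 28 sums for 8 groups in runs 1 to 4, 6 and 7. Sequencing runs served as replicates because the labels name no separate cultures for the pools of one run. edgeR 4.0.16 (R 4.3.3) fitted all 28 sums with group and run as terms, after TMM scaling and its default filter on low counts, and glmQLFTest with Benjamini-Hochberg adjustment called genes at an adjusted p below 0.05. Standard errors were computed from the fold change and the F statistic. The run term follows from the sequencing runs that groups share. Across 7386 genes with a mean of at least 20 CPM, deviations from the group means of sums of the same run correlated at 0.196 to 0.789 in 24 of 24 pairs (median 0.5), against a median of -0.199 in 72 pairs of different runs. Sums of runs 1 and 2, or of runs 3 and 4, also correlated (median 0.232, against -0.295 between these pairs of runs), so the 4 runs may hold fewer independent replicates than 4. In the deposited annotation, 1520 of 1520 wells of empty pools carried equal scatter values in runs 1 and 2. Both AggreWell groups are in run 5, so their pools were the units, as they were in the comparison of AggreWell with monolayer cells. ELS_M7, in run 8 alone, was compared without a test in log2 CPM with an offset of 0.5, for genes with at least 10 counts, and each list's median was placed among 10000 random lists of the same size from 20 bins of expression.

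The 37 gene lists were tested in 9 comparisons with camera of limma 3.58.1 on voom values with a preset correlation of 0.01, adjusted over 323 tests. An estimated correlation and fry were the alternatives. The estimated correlation depends on the order of the samples in weighted fits, so the median p over 21 shuffled orders was taken, a choice made after the data were seen. Shares of cells were counted after thinning each cell to 500 counts, the largest of 3 preset sizes that 80% of the cells in each group reach, or 500 if none. They were compared by exact permutation of runs, or by permutation of pools within runs with 100000 resamples (scipy 1.17.1, numpy 2.4.6). Intervals and limits for counts of 0 cover counting error only. Clusters were made with scanpy 1.11.5 and leidenalg 0.10.2 from counts scaled to 10000 per cell, 2000 variable genes without cell cycle genes, 40 principal components and 20 neighbours at resolution 1. A cluster got a name where at least 3 markers of a cell type were 2-fold higher and in at least 10% of its cells, and at least 2 were among its 10 leading genes. For the overlap of D3 and D8, unchanged groups were simulated 20 times against the shared D1 sums.

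The groups, tests, gene lists, rule for naming genes and the first set of other settings given at the end were fixed before the data were examined. The rule took, in each tested comparison, genes past the threshold with a mean of at least 20 CPM in a group and the same sign in each run (in the AggreWell comparisons, in both sets of pools by number). Of these it named the 12 largest rises and the 12 largest falls, leaving out predicted genes. It added up to 4 members with the smallest adjusted p from each list that passed or had at least 3 changed members, the SUMO pathway members with the largest and smallest change, the 12 largest differences each way for ELS_M7, and the 5 leading genes of each cluster. Where 5 or fewer members of a list changed one way, those outside the rule were named after their values were seen. Some genes that the rule names are not reported here and were left out of the comparison of single samples with their group.

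The tests were tested on simulated data with counts drawn from the real means and library sizes and 200 genes changed. For D3 against D1, 30% of genes changed 1.5-fold were recovered, 72% of those changed 2-fold and 100% of those changed 4-fold. The same figures were 12%, 46% and 98% for Gastruloid_F5 against Gastruloid_F2, 18%, 50% and 90% for ESC_N2B27Lif against D1, and 69.4%, 97.9% and 100% for Gastruloid_AgW against ESC_AgW. Of the unchanged genes 10, 3, 6 and 15 were called.

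The other settings fixed in advance were DESeq2 1.42.0, its size factors in the edgeR fit, no filter on genes, no filter on wells, at least 1000 counts per well, each well thinned before summing, pools as replicates, neighbouring pools summed, no run term, a fit of the compared groups alone, each run left out in turn, other minimum numbers of marker genes, cells not thinned, and cluster resolutions of 0.5 and 2. Those added after the data were seen were wells with at least 2000 counts, runs 1 and 2 and runs 3 and 4 summed, the 2 pools with conflicting labels included as titled, and the cells of the extraembryonic endoderm cluster left out.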

Results

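Single cells of R1, a mouse embryonic stem cell line, were sorted into plates and their messenger RNA was counted by MARS-seq, a method that tags each captured transcript with a molecular identifier before amplification. The cells had or had not been treated with ML-792, an inhibitor of the enzyme that activates SUMO, a small protein that is attached to many nuclear proteins. D1 was untreated cells grown with serum and LIF, D3 followed 48 h of ML-792, D8 followed 5 days without the inhibitor, and D10 followed another 48 h of it. D18 was then washed and kept for 8 days in N2B27 medium with LIF, and ESC_N2B27Lif was untreated cells moved to the same medium. Gastruloid_AgW was D18 cells aggregated for 3 days in AggreWell plates, with ESC_AgW as the untreated counterpart. Gastruloid_F2 and Gastruloid_F5 were D18 cells kept for 2 and 5 days in a droplet device, and ELS_M7 was cells kept for 4 days in the device and 3 days in 20% Matrigel.

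After filtering, 29977 of 32490 sorted wells remained in 171 pools. The wells kept and their median counts were 2173 and 6217 in D1, 2405 and 6058 in D3, 2661 and 6400 in D8, and 2747 and 4224 in D10, each group over runs 1 to 4. ESC_N2B27Lif had 957 wells with a median of 1265 counts in runs 3 and 4, and D18 had 5194 wells with a median of 8762 counts in 6 runs. ESC_AgW and Gastruloid_AgW, both in run 5, had 1389 wells with 3844 counts and 2812 wells with 8653 counts. Gastruloid_F2 and Gastruloid_F5, both in runs 6 and 7, had 2358 wells with 7505 counts and 4408 wells with 6982 counts, and ELS_M7, in run 8 alone, had 2873 wells with 3514 counts. Summed by group and run, totals ranged from 1286533 counts (D1, run 3) to 24160771 counts (Gastruloid_AgW, run 5). Levels below are CPM as mean ± SD over n runs, or over pools for the AggreWell groups, and log2 fold changes carry their standard error. The runs are sequencing runs and the labels name no separate cultures, so the p-values measure a spread that may be partly technical. Each named gene of the comparisons among D1, D3, D8 and D10 moved the same way in 4 of 4 runs unless a number of runs is given.

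Lists of genes fixed in advance were tested as sets with limma's camera, which compares a list with all other genes under a preset correlation. Numbers of members given below are those that passed the filter on counts. Of 323 list tests, 66 passed after Benjamini-Hochberg adjustment. With a correlation estimated from the data, 8 held: posterior Hox, anterior Hox, paraxial mesoderm and fibroblast genes in Gastruloid_F5 against Gastruloid_F2, primitive streak and Wnt feedback genes in Gastruloid_F2 against D18, cholesterol synthesis in ESC_N2B27Lif against D1, and the integrated stress response in Gastruloid_AgW against ESC_AgW. That estimate depends on the order of the samples, so its p-values are medians over 21 orders, in which 3 to 11 lists passed. limma's fry, which tests whether the genes of a list move on balance one way without comparing them with other genes, passed 72 lists, among them 46 of those 66.

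The first comparison asked what 48 h of ML-792 changed. Genes of the 2-cell embryo were among those that rose most. Tcstv3 (ENSMUSG00000095821.2, GRCm38 chromosome 13, 120316878 to 120318178), active at the 2-cell stage, rose from 1.38 ± 0.94 to 65.7 ± 22.7 CPM between D1 and D3 (n = 4 runs each). Its log2 fold change was 5.28 ± 0.513 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 1.36e-07). Zscan4c (ENSMUSG00000054272.6, chromosome 7, 11005745 to 11010547), of a family linked to telomere lengthening, rose from 20.5 ± 11.3 to 391 ± 137 CPM, a log2 fold change of 4.12 ± 0.434. Zscan4a, Zscan4b, Zscan4d, Zscan4e and the deubiquitinase gene Usp17le rose as well, though reads of such close paralogs can be shared between them. Nat8f2 rose from 2.84 ± 2.17 to 75 ± 24.9 CPM, and Serpina3m, Spz1 and the muscarinic receptor gene Chrm3 rose by log2 values of 4.44, 4.37 and 4.31. The heat shock gene Hspa1a rose from 1.34 ± 0.923 to 28.1 ± 27.9 CPM, with run 2 alone at 72.02 and the other runs between 14.03 and 15.68.

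Among the genes that fell, Inhbb (ENSMUSG00000037035.5, chromosome 1, 119415465 to 119422248), which encodes a subunit of activin, went from 102 ± 9.02 to 17.9 ± 6.17 CPM. Its log2 fold change was -2.42 ± 0.25 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 1.65e-07). Krt17, Lrrc34, Tns1, Pdgfc, Coro2b, Fxyd6, Smarcd3, Khdc3 and Fignl2 fell by log2 values between -2.56 and -2.25. In all, 3492 of 15976 genes passed, of which 1990 rose and 1502 fell, and 1650 changed at least 2-fold. Without run 4 the count was 1990.

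Of the 35 genes of the 2-cell list 23 were tested, and 21 of these rose in D3, with none falling, and camera placed the list above other genes (limma's camera with Benjamini-Hochberg adjustment, adjusted p = 1.05e-23; adjusted p = 0.0714 with an estimated correlation). Naive pluripotency genes fell, 14 of 18 over all genes and 15 adjusted over the list alone (limma's camera with Benjamini-Hochberg adjustment, adjusted p = 3.45e-09; adjusted p = 0.245 with an estimated correlation). Tfcp2l1 (ENSMUSG00000026380.10, chromosome 1, 118627945 to 118685168), a transcription factor of naive cells, fell from 291 ± 13.2 to 108 ± 14.6 CPM. Fgf4 fell from 231 ± 25.5 to 67.7 ± 11.6 CPM and Tbx3 from 244 ± 33.6 to 73.1 ± 8.75 CPM, while Dppa3 and Pecam1 of the same list rose. Formative epiblast genes rose in 6 of 16 cases, and in 9 adjusted over the list alone, among them Zic2, Sox4 and Nodal, while Tead2 fell (limma's camera with Benjamini-Hochberg adjustment, adjusted p = 0.0187; adjusted p = 0.424 with an estimated correlation). Dnmt3a (ENSMUSG00000020661.15, chromosome 12, 3806007 to 3914443), which encodes a de novo DNA methyltransferase, rose from 239 ± 22 to 733 ± 202 CPM, and its cofactor gene Dnmt3l rose from 140 ± 25.1 to 287 ± 25.7 CPM. Tet2, whose product oxidises methylcytosine, fell from 257 ± 17.5 to 109 ± 19 CPM.

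Of 18 p53 targets 16 rose and none fell (limma's camera with Benjamini-Hochberg adjustment, adjusted p = 1.26e-12; adjusted p = 0.112 with an estimated correlation). Pmaip1 (ENSMUSG00000024521.8, chromosome 18, 66458533 to 66465565), which promotes cell death, rose from 21.1 ± 7.4 to 97.2 ± 29.5 CPM, and Plk2, Ddit4l and Btg2 rose by log2 values of 2.39, 1.88 and 1.14. Integrated stress response genes fell in 8 of 16 cases (9 adjusted over the list alone), among them the serine synthesis gene Psat1, Nupr1 and Chac1, while Ddit4 and Sesn2 rose (limma's camera with Benjamini-Hochberg adjustment, adjusted p = 0.00791; adjusted p = 0.61 with an estimated correlation). Immediate early genes rose in 4 of 12 cases (5 adjusted over the list alone), namely Jun, Egr1, Fos and Btg2, and none fell (limma's camera with Benjamini-Hochberg adjustment, adjusted p = 0.0209; adjusted p = 0.424 with an estimated correlation). Cholesterol synthesis genes fell in 6 of 19 cases, Msmo1 and Nsdhl among them (limma's camera with Benjamini-Hochberg adjustment, adjusted p = 0.0385; adjusted p = 0.73 with an estimated correlation). In the SUMO pathway list, the protease genes Senp7 and Senp6 rose, Senp3 fell from 171 ± 26.1 to 96.4 ± 26.2 CPM, and the other 18 of 21 genes did not pass. Germline genes moved both ways, with Dazl, Stk31 and Brdt rising and Prdm1 and Mov10l1 falling, and the list's median of -0.0374 differed in sign from its mean of 0.0635.

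The next comparison asked how D8 cells, 5 days after the inhibitor was removed, differed from cells never exposed to it. The genes moved by ML-792 were largely not among those that passed: 69 of 15976 genes did, 57 higher and 12 lower, and 36 at least 2-fold. The count was 4 without run 1, 16 without run 2, 34 without run 3 and 21 without run 4, and 3 with each well thinned to 500 counts. The balance depends on the setting as well, with 117 higher and 53 lower in DESeq2, 39 and 20 in a fit of both groups alone, and 1139 and 903 with pools as replicates. With runs 1 and 2 summed and runs 3 and 4 summed (added after the data were seen), 0 genes passed (edgeR's quasi-likelihood test; 767 had an unadjusted p under 0.05). Sfn (ENSMUSG00000047281.3, chromosome 4, 133600556 to 133602168), a 14-3-3 protein gene of epithelial cells, rose from 22.1 ± 5.59 to 62.6 ± 6.35 CPM (n = 4 runs each). Its log2 fold change was 1.54 ± 0.173 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 5.89e-05). The calcium-binding protein gene S100a6 rose from 43.7 ± 14.5 to 165 ± 108 CPM, the galectin gene Lgals1 from 52.4 ± 7.95 to 121 ± 33.9 CPM, and Gabarapl1, of the autophagy machinery, from 26.6 ± 6.91 to 51.2 ± 11.2 CPM. Anxa3, Lad1, Hmgn5, Rundc3a, Sdc4 and Dcxr rose by log2 values between 0.938 and 1.61. Srgn, a proteoglycan gene abundant in endoderm of the yolk sac, rose from 6.37 ± 2.42 to 36.2 ± 31.1 CPM.

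Among the 12 genes lower in D8, Rpl39l, a ribosomal protein gene of the testis, fell from 101 ± 6.68 to 34.6 ± 11.4 CPM, a log2 fold change of -1.57 ± 0.244 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.00189). Rpl10l fell from 75 ± 8.47 to 36.3 ± 6.6 CPM, the spermatogenesis factor gene Sohlh2 from 59.3 ± 8.87 to 26.1 ± 4.62 CPM, and the RNA-binding protein gene Dazl from 20.9 ± 7.27 to 9.81 ± 2.55 CPM. Myo1f, Gap43 and Morc1 fell as well. Of the 24 tested genes of the germline list (27 listed) Dazl and Rpl10l fell and none rose (limma's camera with Benjamini-Hochberg adjustment, adjusted p = 0.00165; adjusted p = 0.372 with an estimated correlation). Extraembryonic endoderm genes rose in 5 of 20 cases and in 15 adjusted over the list alone, with none falling (limma's camera with Benjamini-Hochberg adjustment, adjusted p = 6.54e-11; adjusted p = 0.0769 with an estimated correlation). They were Srgn, Dab2 (2.73 ± 1.87 to 18 ± 13.9 CPM), Gata6 (2.97 ± 0.725 to 12.4 ± 3.48 CPM), Lamb1 and Cubn, the last in 3 of 4 runs.

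Other lists passed camera in D8 with few or no members passing by themselves, and not with an estimated correlation. The surface ectoderm gene Perp rose, 1 of 4 tested members of 10 (2 adjusted over the list alone), with the list above other genes (limma's camera with Benjamini-Hochberg adjustment, adjusted p = 0.00981; adjusted p = 0.331 with an estimated correlation). None of the 19 cholesterol synthesis genes passed edgeR's test, although camera ranked them above other genes (limma's camera with Benjamini-Hochberg adjustment, adjusted p = 0.000613; adjusted p = 0.497 with an estimated correlation). None of 12 immediate early genes passed over all genes and 2 rose adjusted over the list alone (limma's camera with Benjamini-Hochberg adjustment, adjusted p = 0.0021; adjusted p = 0.275 with an estimated correlation). No SUMO pathway gene passed, with log2 fold changes from -0.475 for Ranbp2 to 0.472 for Pml. D3 and D8 share D1 as control, which alone makes their fold changes correlate. Of the 69 genes, 33 also passed in D3 in the same direction and 5 in the opposite one, against 8.23 same-direction genes that chance gives (n1 × n2 / N) and 0 in 20 simulations with shared controls in which neither D3 nor D8 differed from D1. With no change simulated, few or no calls are expected, so the 0 is no measure of chance at the number called here. In separate fits of D3 in runs 1 and 2 and of D8 in runs 3 and 4, each against D1 of its own runs, 3088 and 761 of 12030 genes passed. These fits differ in more than controls and may take pools as replicates. The 280 shared genes of equal sign (97.15 by chance) and 86 of opposite sign thus decide little. Over all genes the fold changes of D3 and D8 correlated at 0.241, against 0.529 in the simulations, and their covariance was 0.109, against 0.029. Shared controls add the same covariance with or without real changes, whereas real changes in either group can lower the correlation.

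The third comparison asked what a second 48 h of ML-792 did to the recovered cells (D10 against D8). Cyp2b23 (ENSMUSG00000040650.8, chromosome 7, 26665227 to 26686437), a cytochrome P450 gene, rose from 1.99 ± 1.43 to 59.6 ± 11.9 CPM (n = 4 runs each), a log2 fold change of 4.85 ± 0.344 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 9.97e-10). Tcstv3 rose from 1.05 ± 1.28 to 30.2 ± 16.3 CPM, Zscan4c from 17.6 ± 18.2 to 185 ± 107 CPM, and Nat8f2 from 2.13 ± 1.74 to 43.2 ± 12.4 CPM. The transcription factor gene Creb5, the arginase gene Arg2, the semaphorin gene Sema6a, Shisal2b, Zscan4d, Zscan4e, Mep1b and Fam124a rose by log2 values between 2.93 and 4.18. Lrrc34 fell from 37.1 ± 14.1 to 3.45 ± 1.35 CPM and Inhbb from 64.3 ± 27.1 to 12.9 ± 3.71 CPM. Khdc3, Krt17, Sfrp1 (an antagonist of Wnt), Capn5, Smarcd3, Zbtb32 and Ifitm1 fell by log2 values between -2.39 and -2.05. In all, 2824 genes passed, of which 1521 rose and 1303 fell, and 1323 changed at least 2-fold. The count was 1478 without run 1 and 1687 without run 4.

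The lists moved in D10 largely as in D3. Naive genes fell in 13 of 18 cases and in 14 adjusted over the list alone (limma's camera with Benjamini-Hochberg adjustment, adjusted p = 5.23e-11; adjusted p = 0.145 with an estimated correlation), with Tfcp2l1 going from 388 ± 19.8 to 101 ± 10.4 CPM, Tdh from 913 ± 265 to 316 ± 80.4 CPM and Pecam1 alone rising. Of the 2-cell list 18 of 23 genes rose, or 21 adjusted over the list alone (limma's camera with Benjamini-Hochberg adjustment, adjusted p = 4.06e-17; adjusted p = 0.116 with an estimated correlation). Formative genes rose in 7 of 16 cases (8 adjusted over the list alone), Dnmt3a from 226 ± 97.3 to 709 ± 182 CPM (limma's camera with Benjamini-Hochberg adjustment, adjusted p = 0.0021; adjusted p = 0.283 with an estimated correlation). Of 18 p53 targets 12 rose (15 adjusted over the list alone), Pmaip1 and Plk2 among them (limma's camera with Benjamini-Hochberg adjustment, adjusted p = 5.73e-09; adjusted p = 0.266 with an estimated correlation). Cholesterol synthesis genes fell in 10 of 19 cases, or 11 adjusted over the list alone, Nsdhl and Msmo1 among them (limma's camera with Benjamini-Hochberg adjustment, adjusted p = 1.21e-05; adjusted p = 0.339 with an estimated correlation). Imprinted genes rose in 7 of 21 cases, Mirg and Magel2 among them, and Phlda2 fell (limma's camera with Benjamini-Hochberg adjustment, adjusted p = 0.0107; adjusted p = 0.672 with an estimated correlation). In the S phase list Rrm1 and Ung fell, or 6 of 18 adjusted over the list alone (limma's camera with Benjamini-Hochberg adjustment, adjusted p = 0.0262; adjusted p = 0.672 with an estimated correlation). Senp7 and Senp6 again rose, and no other SUMO pathway gene passed.

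Whether the second treatment acted differently from the first was tested for each gene as a difference of fold changes. No gene passed edgeR's quasi-likelihood test, 830 had an unadjusted p under 0.05, and DESeq2 called 3. Zscan4e, which rose by 4.85 in the first treatment and by 3.31 in the second, is an example of a change that was smaller the second time without passing. This difference had the same sign in 3 of 4 runs. Taken as a set, the 2-cell list rose less in the second treatment, with a median difference of -1.16 (limma's camera with Benjamini-Hochberg adjustment, adjusted p = 1.82e-05; adjusted p = 0.576 with an estimated correlation). The p53 targets differed by a median of -0.293 (limma's camera with Benjamini-Hochberg adjustment, adjusted p = 0.000173; adjusted p = 0.554 with an estimated correlation) and cholesterol synthesis by -0.231 (limma's camera with Benjamini-Hochberg adjustment, adjusted p = 0.0262; adjusted p = 0.692 with an estimated correlation). Integrated stress response genes differed by 0.555, and 2 of 16 were higher adjusted over the list alone (limma's camera with Benjamini-Hochberg adjustment, adjusted p = 9.4e-05; adjusted p = 0.395 with an estimated correlation). Across 15976 genes, which are not independent replicates, the fold changes of both treatments had Pearson's r = 0.768, Spearman's rho = 0.712 and a slope of 0.696. Of the genes called in both, 1986 of 1987 moved the same way.

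The share of cells carrying at least 2 genes of the 2-cell list, counted after thinning each cell to 500 counts, put the same change on the level of cells. It rose from 1.548% ± 1.285 in D1 to 16.958% ± 5.355 in D3 (SD, n = 4 runs; exact permutation test, two-sided, p = 0.0286, the smallest possible). It was 0.98% ± 0.8 in D8, a difference from D1 that did not pass (exact permutation test, two-sided, p = 0.571). It reached 6.968% ± 2.627 in D10, above D8 (exact permutation test, two-sided, p = 0.0286). Over D8 the second treatment raised the share by 5.988 ± 2.073 points and over D1 the first raised it by 15.409 ± 4.197 points, a difference of -9.421 (exact permutation test, two-sided, n = 4, p = 0.0286), smaller in 4 of 4 runs. These permutations leave out that the groups share runs, and permutations within 4 runs are too few to pass. Over all cells the share was 0.731% in ESC_N2B27Lif and 0.135% in D18, in each case from 7 cells of run 4 alone. In wells thinned to 2000 counts, none of 344 and 4150 cells reached it. None of 2358 cells of Gastruloid_F2 and 4408 of Gastruloid_F5 did so after thinning to 500 counts, where the exact (Clopper-Pearson) 95% interval reaches 0.156% and 0.084%, and without thinning 1 cell of each group did. These are limits on detection at that depth, not on expression. In pools labelled empty, 0.29% of wells above the count minimum did so by background.

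**Figure D1:**
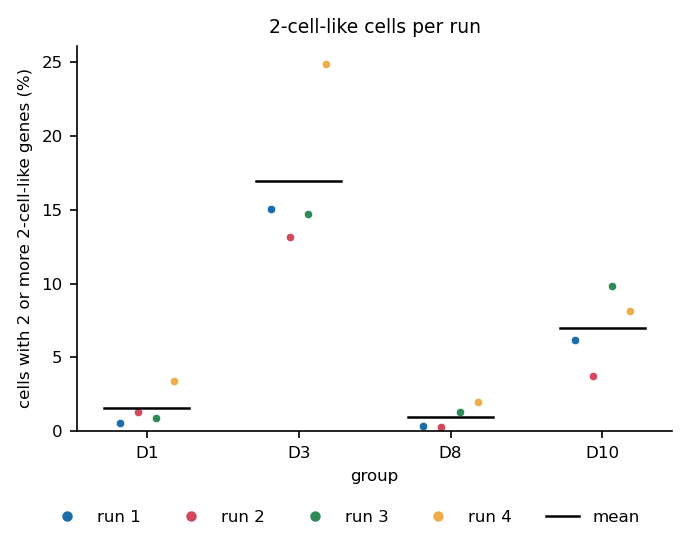
Percent of cells with 2 or more genes of the 2-cell list after thinning to 500 counts, with a point for each of the 4 runs and a line at the mean of D1, D3, D8 and D10. The D3 runs lay between 13.144% and 24.891%, and the D10 runs between 3.72% and 9.833%.

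ESC_N2B27Lif against D1 asked what the change of medium did without the inhibitor, with n = 2 runs for the first group, so D1 levels here are those of the same runs. Cholesterol synthesis genes rose almost throughout. Msmo1 (ENSMUSG00000031604.10, chromosome 8, 64718139 to 64733792), a gene of the later steps of the pathway, rose from 96.5 ± 3.68 to 379 ± 6.65 CPM. Its log2 fold change was 1.99 ± 0.185 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 1.66e-07). Cyp51 rose from 66.3 ± 7.98 to 196 ± 11.5 CPM and Sqle from 36.9 ± 1.89 to 126 ± 21 CPM. Of the list, 18 of 19 rose and none fell (limma's camera with Benjamini-Hochberg adjustment, adjusted p = 1.66e-30, and 0.00958 with an estimated correlation). Otx2 (ENSMUSG00000021848.16, chromosome 14, 48657677 to 48673819), a transcription factor of formative epiblast, rose from 14.2 ± 1.07 to 136 ± 13.7 CPM. Dnmt3b rose from 216 ± 11.1 to 891 ± 18.3 CPM, the kinase gene Pim2 from 25.2 ± 2.75 to 173 ± 50.9 CPM, and Lef1, a mediator of Wnt signals, from 2.65 ± 0.217 to 35.8 ± 12.6 CPM. Pga5, Esrp1, Glod5, Srgn, Rab25, Sema6a, Gpx2, Pmel and Gpa33 rose by log2 values between 2.59 and 3.48.

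Germ cell genes fell in ESC_N2B27Lif, 12 of 24 in the list and 14 adjusted over the list alone, while Stag3 and Prdm1 rose (limma's camera with Benjamini-Hochberg adjustment, adjusted p = 2.07e-06; adjusted p = 0.106 with an estimated correlation). Dazl fell from 25.3 ± 8.87 to 3.84 ± 1.15 CPM and the helicase gene Ddx4 from 34.7 ± 1.51 to 6.28 ± 0.327 CPM. Stra8, a gene of entry into meiosis that is outside the list, fell from 24.4 ± 0.38 to 0.878 ± 0.364 CPM, a log2 fold change of -5.62 ± 1.01 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.000577). Myo1f, Aard, Prrx2, Halr1, Tppp3, Dusp9, Zbtb7c, Igsf21, Fkbp6 and Kank4 fell too, and Inhbb fell from 109 ± 7.84 to 12.1 ± 0.00358 CPM. Extraembryonic endoderm genes rose in 11 of 20 cases, or 12 adjusted over the list alone, Col4a1 and Lama1 among them, and Rbp4 fell (limma's camera with Benjamini-Hochberg adjustment, adjusted p = 1.31e-05; adjusted p = 0.299 with an estimated correlation). Of the 2-cell list 6 of 23 genes fell, or 16 adjusted over the list alone, Zscan4e among them (limma's camera with Benjamini-Hochberg adjustment, adjusted p = 1.21e-05; adjusted p = 0.571 with an estimated correlation). Integrated stress response genes rose in 5 of 16 cases (6 adjusted over the list alone), namely Psat1, Phgdh, Sesn2, Ddit4 and Gdf15 (limma's camera with Benjamini-Hochberg adjustment, adjusted p = 0.00334; adjusted p = 0.565 with an estimated correlation). Neurod1, Ina and Crmp1 of the 12 neuron genes rose (limma's camera with Benjamini-Hochberg adjustment, adjusted p = 0.047; adjusted p = 0.61 with an estimated correlation). Naive genes moved both ways, with Dppa3, Tdh and Morc1 rising and Klf4, Tfcp2l1 and Tbx3 falling, and their median of 0.043 and mean of -0.0169 differed in sign. In all 1791 genes passed, 925 up and 866 down, 1059 at least 2-fold, against 523 without run 3 and 453 without run 4.

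D18 against ESC_N2B27Lif asked what a history of ML-792 treatment left behind in the same medium. Fold changes drew on D18 in 6 runs, whereas the levels given are those of the shared runs 3 and 4 (n = 2 each). Car4 (ENSMUSG00000000805.18, chromosome 11, 84957786 to 84966044), a membrane-bound carbonic anhydrase gene, stood at 79.6 ± 27.5 against 5.63 ± 0.0634 CPM, a log2 fold change of 3.84 ± 0.486 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.000116). H19, an imprinted noncoding RNA, stood at 40.5 ± 8.01 against 5.2 ± 1.21 CPM, and Dppa3, a maternal factor that protects DNA methylation, at 77.7 ± 9.59 against 12.6 ± 0.319 CPM. The endoderm transcription factor genes Gata6 and Sox17 stood at 34.3 ± 0.073 and 22.7 ± 1.39 CPM, against 6.55 ± 3.91 and 3.48 ± 3.85. Chst1, Prtg, Slc39a8, the cyclin gene Ccnd2, Igdcc3, Ndn and Fxyd3 were higher by log2 values between 2.51 and 3.68. Clca3b, Gdf15, Mcf2, Mapk4, Psma8, Hormad2, Gpc3, Zfp518a, Camk1d and Rpl10l were lower by log2 values between -2.02 and -1.5.

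Extraembryonic endoderm genes were higher in D18 in 11 of 20 cases, or 15 adjusted over the list alone, with Sparc at 1187 ± 187 against 441 ± 219 CPM (limma's camera with Benjamini-Hochberg adjustment, adjusted p = 3.46e-12; adjusted p = 0.07 with an estimated correlation). Imprinted genes were higher in 7 of 21 cases, or 12 adjusted over the list alone, H19, Ndn and Snrpn among them (limma's camera with Benjamini-Hochberg adjustment, adjusted p = 0.000741; adjusted p = 0.565 with an estimated correlation). Naive genes had a median of -0.373, yet Dppa3 alone passed and it was higher (limma's camera with Benjamini-Hochberg adjustment, adjusted p = 0.0348; adjusted p = 0.787 with an estimated correlation). Among 9 core pluripotency genes Sox2 and Trim71 were lower, or 4 adjusted over the list alone (limma's camera with Benjamini-Hochberg adjustment, adjusted p = 0.0293; adjusted p = 0.496 with an estimated correlation). Among 24 germline genes Stag3, Rpl10l and Prdm1 were lower (limma's camera with Benjamini-Hochberg adjustment, adjusted p = 0.0135; adjusted p = 0.533 with an estimated correlation). Runx1 was higher among 11 endothelium and blood genes, or 3 adjusted over the list alone (limma's camera with Benjamini-Hochberg adjustment, adjusted p = 0.047; adjusted p = 0.424 with an estimated correlation). In the SUMO pathway list Senp7 was higher and 2 genes were lower, Morc3 among them. In all 1343 genes passed, 718 higher and 625 lower, 631 at least 2-fold, against 34 without run 3 and 92 without run 4, of which 79 were higher and 13 lower. With no filter on genes 995 were higher and 548 lower. With runs 1 and 2 summed and runs 3 and 4 summed, 3 genes passed.

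Gastruloid_F2 against D18 asked what 2 days in the droplet device changed. Genes of the primitive streak and caudal epiblast rose. T (ENSMUSG00000062327.10, chromosome 17, 8434423 to 8442496), the brachyury gene of the streak, rose from 8.05 ± 0.952 to 187 ± 60.5 CPM (n = 2 runs each), a log2 fold change of 4.53 ± 0.44 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 3.14e-06). Hoxc10 (ENSMUSG00000022484.7, chromosome 15, 102966796 to 102971893) rose from 0.974 ± 0.544 to 28.1 ± 20.6 CPM, Sp5, a target of Wnt signals, from 15.7 ± 5.46 to 171 ± 52.9 CPM, and Nkx1-2 from 9.45 ± 4.31 to 145 ± 121 CPM. Hoxb1, Cdx1, Cdx2, Hes3, Fzd10, Apln, Wnt5a and Sall3 rose by log2 values between 2.53 and 4.19. Otx2 fell from 80.3 ± 44 to 19.9 ± 8.66 CPM, the basement membrane gene Col4a1 from 156 ± 68.3 to 33.7 ± 4.68 CPM, Nupr1 from 73.4 ± 32.4 to 9.09 ± 4.43 CPM and Srgn from 21.4 ± 16.8 to 1.46 ± 0.571 CPM. Tagln, Pga5, Col4a2, Cebpb, Cldn7, Glod5, Anxa2 and Mef2b fell by log2 values between -3.97 and -1.6. In all 388 genes passed, 200 up and 188 down, 272 at least 2-fold, against 47 without run 6 and 162 without run 7.

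Of 12 primitive streak genes 7 rose in Gastruloid_F2, or 10 adjusted over the list alone, Axin2 and Fgf8 among them (limma's camera with Benjamini-Hochberg adjustment, adjusted p = 8.74e-15, and 0.0447 with an estimated correlation). Caudal genes rose in 8 of 14 cases, or 10 adjusted over the list alone, Cdx1 and Wnt5b among them (limma's camera with Benjamini-Hochberg adjustment, adjusted p = 6.15e-12; adjusted p = 0.0867 with an estimated correlation). Wnt and FGF feedback genes rose in 5 of 15 cases, or 8 adjusted over the list alone (limma's camera with Benjamini-Hochberg adjustment, adjusted p = 3.2e-10, and 0.0447 with an estimated correlation), namely Axin2, Sp5, Nkd1, Id3 and Lefty1. Extraembryonic endoderm genes fell in 7 of 20 cases, or 14 adjusted over the list alone, Col4a2 and Lama1 among them, while Fst rose (limma's camera with Benjamini-Hochberg adjustment, adjusted p = 1.21e-05; adjusted p = 0.298 with an estimated correlation). A cluster led by such genes held 3.98% ± 2.64 of D18 in 6 runs and 0.13% ± 0.19 of Gastruloid_F2 in runs 6 and 7, not matched by run or tested. Integrated stress response genes fell in 6 of 16 cases, or 9 adjusted over the list alone, among them Asns from 1319 ± 338 to 743 ± 5.77 CPM (limma's camera with Benjamini-Hochberg adjustment, adjusted p = 2.67e-10; adjusted p = 0.0867 with an estimated correlation). Anterior Hox genes rose in 2 of 16 cases, Hoxb1 and Hoxb2, or 6 adjusted over the list alone (limma's camera with Benjamini-Hochberg adjustment, adjusted p = 0.000315; adjusted p = 0.549 with an estimated correlation). Among 19 posterior Hox genes Hoxb8, Hoxb9 and Hoxc10 rose and Hoxc11 fell, or 6 and 2 adjusted over the list alone (limma's camera with Benjamini-Hochberg adjustment, adjusted p = 0.0149; adjusted p = 0.275 with an estimated correlation).

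Other lists passed camera in Gastruloid_F2 with few or no members passing by themselves, and not with an estimated correlation. Fabp7 rose among 12 neural progenitor genes, or 3 adjusted over the list alone (limma's camera with Benjamini-Hochberg adjustment, adjusted p = 0.00012; adjusted p = 0.423 with an estimated correlation). Dll3 rose among 14 paraxial mesoderm genes, or 5 adjusted over the list alone (limma's camera with Benjamini-Hochberg adjustment, adjusted p = 0.0156; adjusted p = 0.496 with an estimated correlation). Aen rose among 18 p53 targets, or 3 adjusted over the list alone (limma's camera with Benjamini-Hochberg adjustment, adjusted p = 0.0135; adjusted p = 0.73 with an estimated correlation). Msmo1 fell among cholesterol synthesis genes (limma's camera with Benjamini-Hochberg adjustment, adjusted p = 0.0206; adjusted p = 0.672 with an estimated correlation) and Hmmr among genes of G2 and M phase (limma's camera with Benjamini-Hochberg adjustment, adjusted p = 0.026; adjusted p = 0.733 with an estimated correlation). No S phase gene passed, although the list ranked above other genes (limma's camera with Benjamini-Hochberg adjustment, adjusted p = 0.0268; adjusted p = 0.672 with an estimated correlation).

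Gastruloid_F5 against Gastruloid_F2 asked what changed between days 2 and 5 in the device. Hox genes of the trunk rose across the 4 clusters, together with somite and mesenchyme genes. Hoxd10 (ENSMUSG00000050368.4, chromosome 2, 74691924 to 74695105) rose from 0.31 ± 0.439 to 24.2 ± 3.94 CPM (n = 2 runs each), a log2 fold change of 6.37 ± 0.61 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 6.37e-07). Hoxc9 (ENSMUSG00000036139.6, chromosome 15, 102976439 to 102985099) rose from 3.66 ± 2.19 to 97.4 ± 53.3 CPM, and Hoxa9, Hoxa10, Hoxc6, Hoxd8 and Hoxd9 rose by log2 values between 4.44 and 5.08. Hoxb5os, which is antisense to Hoxb genes, rose too, and its reads may be shared with them. Meox1, a gene of somites, rose from 2.53 ± 2.39 to 94.6 ± 77.6 CPM, the growth factor binding protein gene Igfbp5 from 5.63 ± 2.17 to 143 ± 65.6 CPM, H19 from 23.5 ± 5.6 to 512 ± 186 CPM, and Foxc2 from 1.28 ± 1.52 to 24.3 ± 24.3 CPM. Pim2 fell from 337 ± 10.8 to 39.2 ± 0.434 CPM, a log2 fold change of -3.1 ± 0.195 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 2.75e-10). Dnmt3b fell from 504 ± 126 to 112 ± 15.4 CPM and the carbonic anhydrase gene Car2 from 221 ± 105 to 32.9 ± 3.95 CPM. Car3, Rxrg, Kcnj3, Apln, Rpl39l, Khdc3, Tcfl5, Exoc3l, S100a6 and Alox15 fell by log2 values between -3.01 and -2.18. In all 1562 genes passed, 877 up and 685 down, 899 at least 2-fold, against 244 without run 7.

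**Figure D2:**
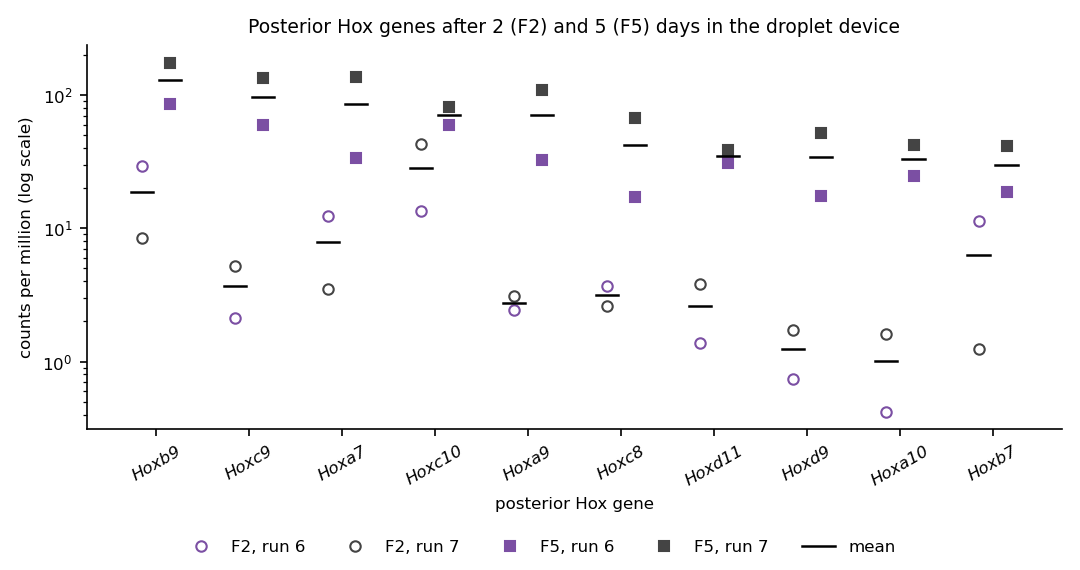
CPM (log axis) of 10 posterior Hox genes in Gastruloid_F2 (open circles) and Gastruloid_F5 (filled squares), with a point for each of runs 6 and 7. Hoxc9 averaged 3.66 CPM in Gastruloid_F2 and 97.4 CPM in Gastruloid_F5.

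Posterior Hox genes rose in 17 of 19 cases in Gastruloid_F5, or 18 adjusted over the list alone (limma's camera with Benjamini-Hochberg adjustment, adjusted p = 7.56e-25, and 8.14e-05 with an estimated correlation). Anterior Hox genes rose in 14 of 16 cases (limma's camera with Benjamini-Hochberg adjustment, adjusted p = 2.79e-19, and 0.0477 with an estimated correlation). Paraxial mesoderm genes rose in 8 of 14 cases, Foxc1, Aldh1a2 and Meox1 among them (limma's camera with Benjamini-Hochberg adjustment, adjusted p = 2.8e-10, and 0.0447 with an estimated correlation). Isl1, Msx2, Twist1, Prrx1 and Prrx2 rose among 13 genes of lateral and cardiac mesoderm (limma's camera with Benjamini-Hochberg adjustment, adjusted p = 0.00974; adjusted p = 0.0769 with an estimated correlation). Of 7 neural crest genes Sox10, Snai2 and Ets1 rose, or 5 adjusted over the list alone (limma's camera with Benjamini-Hochberg adjustment, adjusted p = 0.00028; adjusted p = 0.0714 with an estimated correlation). Of 12 neural progenitor genes Irx3, Zic1, Pantr1 and Sox9 rose, or 8 with 1 lower adjusted over the list alone (limma's camera with Benjamini-Hochberg adjustment, adjusted p = 9.72e-05; adjusted p = 0.418 with an estimated correlation). The fibroblast list, which holds collagens, rose in 5 of 9 cases, Col1a1, Col1a2, Col3a1, Loxl1 and Pdgfrb, and Thy1 fell (limma's camera with Benjamini-Hochberg adjustment, adjusted p = 0.000741, and 0.0447 with an estimated correlation). Neuron genes fell in 5 of 12 cases, Stmn2 and Ina among them, while Neurog1 rose, and their median of -0.426 differed in sign from their mean of 0.0429.

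The core pluripotency, heat shock and S phase lists ranked below other genes in Gastruloid_F5 by camera, with few members passing and not with an estimated correlation. Core pluripotency genes fell in 3 of 9 cases, Sall4 and Lin28a among them, or 5 adjusted over the list alone (limma's camera with Benjamini-Hochberg adjustment, adjusted p = 0.00553; adjusted p = 0.339 with an estimated correlation). Hsph1 and Hspb1 fell among 10 heat shock genes (limma's camera with Benjamini-Hochberg adjustment, adjusted p = 0.0113; adjusted p = 0.106 with an estimated correlation), and Ccne1 among 18 S phase genes (limma's camera with Benjamini-Hochberg adjustment, adjusted p = 0.00897; adjusted p = 0.601 with an estimated correlation). Asns, Nupr1 and Gdf15 rose among 16 genes of the integrated stress response, or 5 adjusted over the list alone (limma's camera with Benjamini-Hochberg adjustment, adjusted p = 0.0403; adjusted p = 0.715 with an estimated correlation). In the SUMO pathway Senp7 rose, while Sumo3, Senp3 and the corepressor gene Trim28 fell.

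Gastruloid_AgW against ESC_AgW asked how aggregates of cells with and without a history of ML-792 differed. The units were 15 and 8 pools of run 5, so the spread is that between pools of one plate set. Aggregates from treated cells had more transcripts of streak and neural progenitor genes and fewer of naive genes. Ndufa4l2 (ENSMUSG00000040280.10, chromosome 10, 127514967 to 127517154), which is induced by low oxygen, stood at 89.8 ± 22.3 against 5.11 ± 4.42 CPM, a log2 fold change of 4.28 ± 0.243 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 1.15e-14). T stood at 42.5 ± 17.6 against 3.8 ± 4.08 CPM, Fgf8 at 34.1 ± 13.6 against 2.1 ± 2.42, Sp5 at 68.5 against 3.73, Nkx1-2 at 92.2 ± 18.5 against 5.72 ± 6.92, and Ccnd2 at 339 ± 25 against 23.3 ± 21.3 CPM. Alox15, Mogat2, Nt5e, Ptn, Apln and Greb1 were higher too. The Nodal antagonist gene Lefty2 stood at 114 ± 41 against 566 ± 70.8 CPM and the interferon-induced gene Ifitm3 at 134 ± 28.7 against 557 ± 65. Clca3b, Aoah, Nkx6-3, Nqo1, Kbtbd11 and Lgals3 were lower by log2 values between -2.57 and -1.94. In all 5210 of 10376 genes passed, 2634 higher and 2576 lower, 1163 at least 2-fold.

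Naive genes were lower in Gastruloid_AgW in 15 of 18 cases, with Zfp42 at 143 ± 28.6 against 439 ± 38.6 CPM and Nr0b1 at 100 ± 30.8 against 257 ± 39.8 (limma's camera with Benjamini-Hochberg adjustment, adjusted p = 1.06e-07; adjusted p = 0.0769 with an estimated correlation). Klf4 was higher, and Nanog and Dppa3 did not pass. All 7 streak genes measured were higher (limma's camera with Benjamini-Hochberg adjustment, adjusted p = 9.1e-06; adjusted p = 0.0669 with an estimated correlation), as were all 5 neural progenitor genes measured, Sox1, Nes, Fabp7, Irx3 and Ptn (limma's camera with Benjamini-Hochberg adjustment, adjusted p = 8.04e-05; adjusted p = 0.0769 with an estimated correlation). Formative genes were higher in 10 of 15 cases, Sox3 and Lef1 among them, and Nodal and Tdgf1 were lower (limma's camera with Benjamini-Hochberg adjustment, adjusted p = 0.00756; adjusted p = 0.432 with an estimated correlation). Imprinted genes were higher in 13 of 19 cases, Ndn and Sgce among them, and Cdkn1c and Phlda2 were lower (limma's camera with Benjamini-Hochberg adjustment, adjusted p = 4.96e-05; adjusted p = 0.0769 with an estimated correlation). Glycolysis genes were higher in 8 of 13 cases, or 9 adjusted over the list alone, with Ldha at 2932 ± 276 against 565 ± 131 CPM, and Hk2 was lower (limma's camera with Benjamini-Hochberg adjustment, adjusted p = 7.18e-05; adjusted p = 0.0531 with an estimated correlation). Integrated stress response genes were higher in 13 of 15 cases, Atf5 and Chac1 among them, and Sesn2 and Gdf15 were lower (limma's camera with Benjamini-Hochberg adjustment, adjusted p = 2.25e-05, and 0.0337 with an estimated correlation). In the SUMO pathway Senp7 and Pias1 were higher, and 9 of 21 genes, Pml among them, were lower.

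**Figure D3:**
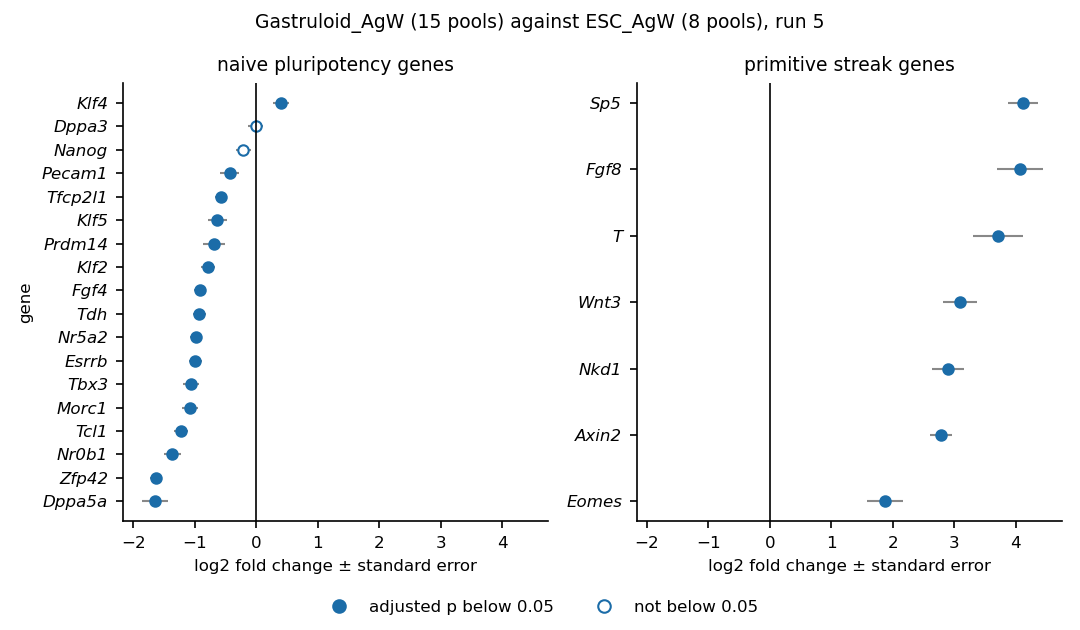
Log2 fold change of Gastruloid_AgW against ESC_AgW for 18 naive and 7 primitive streak genes, with bars of 1 standard error and filled points for an adjusted p below 0.05. The 7 streak genes lay above 0, T at 3.71, and 15 naive genes lay below it, Zfp42 at -1.63.

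Cells carrying at least 3 genes of a marker list were counted after thinning to 500 counts. Naive cells made up 24.862% ± 3.837 of Gastruloid_AgW pools and 46.135% ± 4.121 of ESC_AgW pools (permutation test, two-sided, p = 1e-05, the smallest possible; adjusted p = 0.00038 by Benjamini-Hochberg over 38 tests). Among the 87 wells without a sorted cell that reached the count minimum, 31.034% carried the naive genes too. Cells with formative genes made up 4.793% against 2.483%, a difference of 2.31 points (permutation test, two-sided, adjusted p = 0.0167 by Benjamini-Hochberg), at or below the 9.195% of the wells without a cell. In Gastruloid_F5 against Gastruloid_F2, formative cells were fewer by -1.205 points, paraxial mesoderm cells more by 0.7 and neural progenitor cells more by 0.891 (permutation test, two-sided, adjusted p = 0.0382, 0.017 and 0.0375 by Benjamini-Hochberg), with pools of 2 runs as units. Of the 87 wells without a cell, 9.195% carried the formative genes and none those of the other panels named. None of these wells came from runs 6 and 7, however, so they do not measure the background of Gastruloid_F2 and Gastruloid_F5. With at least 4 genes per cell none of these 3 differences of Gastruloid_F5 passed.

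Whether the history of treatment had a different effect in aggregates than in monolayers was tested by setting Gastruloid_AgW against ESC_AgW beside D18 against ESC_N2B27Lif, with pools as units and each pair in its own runs. In all 2958 of 10658 genes differed, 1400 more positive and 1558 more negative in aggregates, and 1095 by at least 2-fold. Ndufa4l2 stood at 91.2, 5.25, 2.8 and 5.98 CPM in Gastruloid_AgW, ESC_AgW, D18 and ESC_N2B27Lif, a log2 difference of 5.47 ± 0.583 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 1.45e-09). Sp5 stood at 69.6, 3.84, 13 and 13.2 CPM, and Sall3, Grb10, Bnip3, Efnb1, Gbx2, Lef1, Stc2, Lrrn2, Axin2 and Greb1 differed by log2 values between 2.61 and 3.72. S100a6 went the other way, at 30.7, 89.8, 276 and 54.5 CPM, a log2 difference of -3.84 ± 0.244. Ifitm3 stood at 136, 572, 179 and 96.6 CPM and Dppa3 at 64.2, 64, 77.4 and 11.3 CPM, and Pla2g7, Chst1, Nkx6-3, Krt8, Patl2 and Lgals9 were also more negative in aggregates. Across 10375 genes, which are not independent replicates, the fold changes in aggregates and monolayers had Pearson's r = 0.604 and Spearman's rho = 0.496.

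ELS_M7 was sequenced in a run of its own with no replicate and no other group, so its levels are set beside Gastruloid_F5 without a test, and the run and the group cannot be told apart. Of 8607 genes at 20 CPM or more in either group, 539 were at least 2-fold higher and 730 at least 2-fold lower. Sox10, a neural crest gene, stood at 70.1 against 0.745 CPM, and Actc1, a heart and muscle actin, at 110 against 1.94 CPM. Adm, Hic1, Rarb, Cbln2, Wnt1, Spon1, Bnip3, Ndufa4l2, Ttn and Pcdh9 were higher by log2 values between 4.02 and 5.37. Trh stood at 39 against 874 CPM, Tdh at 68.8 against 896, Tfcp2l1 at 35.5 against 377 and Dppa3 at 0.978 against 36.2 CPM. Trpm1, Slc4a5, Spp1, Fgf17 and Tdrd12 were lower by log2 values between -3.73 and -3.28. The naive list had a median of -2.66 and the core list -1.43, both at percentile 0 (rounded to 0.1) among 10000 random lists matched on size and expression. Neural progenitor genes were higher in 15 of 16 cases, with a median of 1.54, neural crest genes in 9 of 9, with a median of 1.9, and neurons and fibroblast genes had medians of 1.57 and 1.93, each at percentile 100 among the random lists. Glycolysis genes had a median of 1.05 and imprinted genes 0.782, at the same percentile, and germline (-1.22), trophoblast (-1.35) and integrated stress response genes (-1.1) lay at percentile 0. With Gastruloid_F5 of run 6 alone, the streak list moved from -1.71 to -0.0206, the caudal list from -1.12 to -0.406, the mitochondrial list from -1.12 to 0.345, the lateral mesoderm list from 0.233 to 1.73 and endothelium from 0.141 to 1.08.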

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

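Both tests on the depth and the runs behind the 2-cell share were chosen after the result was seen, and the others here were planned. The share of cells with at least 2 genes of the 2-cell list rose less in the second ML-792 treatment (D10 against D8) than in the first (D3 against D1), by -9.421 points (exact permutation test, two-sided, n = 4 runs, p = 0.0286, the smallest possible). The share was lower in D10 than in D3 in 4 of 4 runs, with a ratio of 0.283 to 0.668, which argues against a difference between sequencing runs, since each run holds both groups. D10 cells were sequenced less deeply than D3 cells, at medians of 4224 and 6058 counts. Among wells with at least 2000 counts, each thinned to 2000, the share was again lower in D10 in 4 of 4 runs, with means over runs of 16.2% against 33.2%, and the difference of the effects was -16.238 points. A difference in depth therefore does not account for it. A memory of the first treatment in the cells is 1 explanation these tests leave open, and a second dose that acted less, the selection of cells between the treatments and a different culture are others, none of which was tested. No gene of the list passed the test of the difference by itself, with 0 genes past edgeR's quasi-likelihood test, 830 at an unadjusted p under 0.05 and 3 called by DESeq2. Any split of the samples gives at least 0, so 40 of 40 splits with as many, the real one included (highest other 5), say nothing about chance.

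The D3 share of 24.89% in run 4 stood apart from the other D3 runs, which lay between 13.14% and 15.07%. Without run 4 the difference between treatments was -7.464 points. In D18 the share was 0.962% in run 4 and 0 in the other 5 runs. D18 in run 3 also kept 68.9% of its sorted wells, against 95.8% to 100% in its other runs. Hspa1a, a heat shock gene, reached 72.02 CPM in D3 of run 2, against 14.03 to 15.68 in the other runs. Fignl2 stood at 2.478 CPM in D3 of run 2, against 5.117 to 5.406. In D1 of run 4, Pdgfc stood at 29.48 CPM, against 19.43 to 20.84, and Rpl39l at 113.2, against 96.34 to 98.25. In pool 28 of ESC_AgW, Ndufa4l2 stood at 13.69 CPM, against 1.333 to 6.933 in the other pools, and Fgf8 at 6.845, against 0 to 2.553. These 9 were found among 175 sets of values, where chance gives about 1 in 20, or 8.8.

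The effect of a history of ML-792 differed between aggregates and monolayers at 2958 genes, among them Ndufa4l2, Sp5 and S100a6. Among splits of the same pools the real grouping was the only 1 of 40 with as many genes and the highest other had 1670, which excludes chance among pools but not a chance difference between cultures. The aggregates and the monolayers were sequenced in different runs, and each history effect was taken within its own runs. A spread between pools stands in for that between cultures, so the number of genes may be overstated.

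Side scatter, which rises with the granularity of cells, was not part of the comparisons. Its median per run was higher in D3 than in D1 (mean ratio 1.318), in D8 than in D1 (1.279) and in D10 than in D8 (1.154), in each case in 4 of 4 runs. The differences did not pass a test that leaves out that the groups share runs (exact permutation test, two-sided, n = 4 runs, p = 0.0571 in each case, above the smallest possible of 0.0286). This does not show that the groups were alike, and a permutation within 4 runs is too small to pass.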

How the results depend on the processing

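Wells with at least 2000 counts, summed pairs of runs, the pools with conflicting labels included as titled and the omission of the extraembryonic endoderm cluster, like the shuffled orders of samples in the list tests, were tests chosen after the data were seen, and the others were planned. For the counts and summary values of the comparisons, 130 of 201 alternatives stayed on the same side (within 1.5 times for counts), 63 moved, 8 no longer passed and none reversed. Of 7932 checks of named genes, 6904 kept direction and call, 1023 no longer passed and 5 reversed. All 120 checks of the ELS_M7 genes kept direction. The cause was not tested except where the setting itself removes counts or samples.

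Thinning each well to 500 counts before summing removes most counts, and fewer genes passed: 451 for D3 against D1, 3 for D8 against D1, 283 for D10 against D8, 146 for ESC_N2B27Lif against D1, 28 for D18 against ESC_N2B27Lif, 27 for Gastruloid_F2 against D18, 266 for Gastruloid_F5 against Gastruloid_F2, 556 for Gastruloid_AgW against ESC_AgW and 128 for the difference of history effects. The 5 reversals arose there, with the log2 fold change now -0.452 in Dusp4, D8 versus D1, 0.63 in Dab2, D10 versus D8, -0.098 in Sgce, D10 versus D8, 0.153 in Lefty2, D10 versus D8, and -0.196 in Dab2, Gastruloid_F5 versus Gastruloid_F2. Depth thus limits how many genes pass, and wells with at least 2000 counts kept the counts of genes within 1.5 times.

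Fewer replicates also lowered the counts. With runs 1 and 2 summed and runs 3 and 4 summed, 1264 genes passed for D3, 0 for D8 (edgeR's quasi-likelihood test; 767 had an unadjusted p under 0.05), 745 for D10, 301 for ESC_N2B27Lif, 3 for D18, 82 for Gastruloid_F2 and 933 for Gastruloid_F5. Leaving out 1 run at a time gave 1990 to 2697 genes for D3, 4 to 34 for D8, 1478 to 1927 for D10, 453 to 523 for ESC_N2B27Lif, 34 to 92 for D18, 47 to 162 for Gastruloid_F2 and 244 to 1242 for Gastruloid_F5. Where it left 1 sum in a group, that sum was taken to vary like the other groups. Leaving out a run, the 2-cell share rose by 13.389 to 16.604 points in D3 and by 5.147 to 6.836 points in D10, where 3 runs against 3 cannot go below p = 0.1. With pools as replicates, which treats pools of one run as independent, 2042 genes passed for D8, 4961 for D10, 397 for the second against the first treatment, 3758 for ESC_N2B27Lif, 4206 for D18, 4217 for Gastruloid_F2 and 6138 for Gastruloid_F5. Calls of D3 and D8 then shared 725 genes.

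With no run term, 23 genes passed for D8, 763 for D18, 609 for Gastruloid_F2 and 834 for Gastruloid_F5. The other counts stayed within 1.5 times. Fitting only the groups compared gave 4218 for D18 and 344 for Gastruloid_F5. With no filter on genes, 281 passed for D8, 52 for the second against the first treatment and 704 for Gastruloid_F2. DESeq2 called 170 for D8 and 3 for the second against the first treatment. Without the cells of the extraembryonic endoderm cluster, 36 passed for D8. No scaling moved the median of all genes by more than 0.0631 on the log2 scale. The correlation of the first and second treatment effects was 0.855 for genes of at least 20 CPM and 0.836 with pools, and that of aggregates and monolayers 0.521 for genes of at least 20 CPM. At resolution 0.5 there were 10 clusters.

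List tests lost most with an estimated correlation, which kept 8 of 66, among them posterior Hox genes in Gastruloid_F5 and cholesterol synthesis in ESC_N2B27Lif. In 21 sample orders, 3 to 11 passed. Among 19 marker panels, 2 had different shares of cells in Gastruloid_AgW and ESC_AgW, against 4 with at least 2 genes per cell, 1 with at least 4, 10 without thinning and 7 in wells thinned to 2000 counts. For Gastruloid_F5 against Gastruloid_F2 the 3 became 8, 0, 11 and 9 (permutation test of pools for the 0, with 2 panels at an unadjusted p under 0.05).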

Other observations

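Leaving out the extraembryonic endoderm-like cells, keeping wells with at least 2000 counts, summing pairs of runs and taking all members of 2 lists within each run were tests chosen after the data were seen, and the other tests in this part were planned. Clustering 29977 cells gave 17 groups, of which 5 met the rule for a name. Cluster 2 was naive-like on 3 markers (2791 cells, led by S100a6 and Dppa3), though unnamed cluster 5 had 8. Cluster 7 was formative-like (2141 cells, led by Car4). Cluster 15 was 2-cell-like, with 580 cells led by Zscan4a and its relatives. Cluster 13 was neural progenitor-like (978 cells; Msx3, Hes5, Pantr1, Pou3f3 and Miat), and 93.8% of it came from ELS_M7. Cluster 17 was extraembryonic endoderm-like (280 cells; Srgn, Col4a1, Col4a2, Lama1 and Sox17). Without a name, cluster 8 was led by H19, Col3a1, Tgfbi, Nr2f2 and Igfbp5 and was 91.8% ELS_M7, cluster 9 by Hoxb5os, Hoxaas3, Hoxb9, Hoxa7 and Hoxb1 and was 89.5% Gastruloid_F5, and cluster 12 by genes that include Pim2, Wnt8a, Fgf8 and Ndufa4l2 and was 95.5% Gastruloid_AgW. In wells with at least 2000 counts 22 clusters formed, 1 of them endothelium-like with 26 cells led by Plxnd1, Igfbp3, Cd93, Icam2 and Apold1.

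The 8 pools of run 6 that entered no comparison are titled only as gastruloids, and the deposited annotation names them Gastruloid_AgW. They held wells with a median of 9521 counts, and 97.5% of their sorted wells had at least 2000. T stood between 108.1 and 217.0 CPM in these samples (median 178.8), Nkx1-2 between 186.4 and 223.2 (208.2), Sp5 between 124.1 and 155.5 (141.9) and Lefty2 between 196.2 and 331.2 (281.8). Fgf8 had a median of 48.8 CPM, Ptn 177.6, Ccnd2 529.1, Ifitm3 124.0 and Ndufa4l2 10.4 (5.8 to 15.4). Computed in the same way, the pools of Gastruloid_AgW in run 5 had T between 21.6 and 81.5 CPM (41.8), Nkx1-2 between 60.7 and 126.5 (99.7) and Ndufa4l2 between 60.9 and 141.2 (90.5), which do not overlap, and Fgf8 between 13.7 and 61.1 (38.2) and Ifitm3 between 98.5 and 173.0 (136.8), which do. Of 24 genes 16 had ranges that overlap. The pools differ in run as well, and whether the deposited name is right was not tested.

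A small set of extraembryonic endoderm-like cells was tested as a source of genes higher after treatment. Of the 57 genes higher in D8 than in D1, 28 passed without the cells of cluster 17, and the median log2 fold change went from 0.926 to 0.901 at a standard error of 0.186 and 0.192. Srgn went from 2.51 to 0.334, Cubn from 4.01 to 1.23 and Gata6 from 2.07 to 1.2, and they no longer passed. S100a6 (1.79 and 1.81), Sfn (1.54 and 1.55) and Lgals1 (1.21 and 1.22) did not move, which argues against such cells as the source of these. Of the 11 extraembryonic endoderm genes higher in D18 than in ESC_N2B27Lif, 1 passed without the cluster, Sparc. All 11 shrank, Gata6 from 2.55 to 0.862 and Dab2 from 1.44 to 1.34, and their median from 1.66 to 1.34. Precision fell too (standard error 0.436, then 0.591). Whether cells outside the cluster carry these genes at a low level is open, because clustering assigns such cells to other clusters and leaves too few counts of Gata6 or Sox17 to decide. With at least 2000 counts per well 10 of the 11 passed (median 1.71), but depth can still differ and stays open. The cluster held 0.22% ± 0.25 of D1 cells, 0.71% ± 0.29 of D8, 1.31% ± 0.32 of ESC_N2B27Lif and 3.98% ± 2.64 of D18 (mean and SD over runs, not tested). Cells of this kind may account for part of what D8 and D18 show, which these tests do not decide.

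Cholesterol synthesis genes higher and germline genes lower in ESC_N2B27Lif than in D1 were weighed against depth and run. ESC_N2B27Lif wells were shallow, yet 30 of 30 genes (18 of cholesterol synthesis and 12 of the germline) passed in wells with at least 2000 counts, with a median size of 1.11 against 1.1. Shallow wells are therefore not the source of the pattern. They add a minor part of the summed counts, however, and the minimum does not make the groups equal in depth, so a difference in depth stays open. That 30 of 30 had the same sign in runs 3 and 4 decides nothing, since these genes were chosen on the same runs. Over all tested members, the median log2 difference was 1.36 ± 0.166 in run 3 and 1.38 ± 0.144 in run 4 for 19 cholesterol synthesis genes, and -0.755 ± 0.373 and -0.677 ± 0.274 for 24 germline genes (with standard errors over genes). All 4 medians lay beyond 2 standard errors, those of the germline narrowly. Genes are not independent and both lists passed on these runs, so run stays open. The medium, which the design names, was not tested as an explanation.

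Other splits of the same samples exclude chance for D3 against D1 if the 8 samples are taken as independent, since the real grouping, with 3492 genes, was the only 1 of 35 with as many and the highest other had 89. The same holds for D10 against D8 (1 of 35; 2824 genes, highest other 264) and, by a narrow margin, for D8 against D1 (1 of 35; 69 genes, highest other 44). The groups share runs, however, and only 8 splits keep 1 sample of each run on each side, too few for a share under 0.05. Among these the highest other had 0 genes for D3, 0 for D10 and 44 for D8. Runs 1 and 2 and runs 3 and 4 may not be independent either. With these pairs summed 1264 genes passed for D3, 745 for D10 and 0 for D8 (edgeR's quasi-likelihood test; 767 had an unadjusted p under 0.05), so chance stays open for D8. For Gastruloid_AgW against ESC_AgW (1 of 60; 5210 genes, highest other 2060) the splits exclude chance among the pools of run 5. They do not exclude a chance difference between the cultures, for which the labels name no replicates.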
